A study of Mus musculus with 3 samples.

How the data were processed

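ATAC-seq peak lists of 2 libraries of callosal projection neurons (CPN 1 and CPN 2) and 1 library of corticospinal motor neurons (CSMN) from mouse brain were analysed. Sorted cells were lysed, nuclei were incubated with transposase and the fragments were amplified, per the labels' protocols. The labels call each sort a biological replicate, and the age and strain of the mice were not given in the sources used here. The submitters' processing notes name BWA 0.7.17, MACS2 2.2.7.1, bedtools 2.29.2 and the mouse genome build mm10, without saying which step each served. Read filters, removal of duplicates, the shift of reads for the transposase, the peak caller's mode and any list of excluded regions were not given in the sources used here. Each deposited list carries the name of a single library in its peak names, so the authors' peaks were taken as called per library and not on pooled reads.

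The deposited lists give for each peak a fold enrichment at the summit, a −log10 p and a −log10 q, and these are the authors' values. The score deposited with each peak was checked on the files to be 10 times its −log10 q, cut to a whole number. The deposited lists also hold the offset of the summit from the peak's start, in bp. The lowest −log10 q was 1.31 in CPN 1, 1.31 in CPN 2 and 1.30 in CSMN, which shows the threshold of the lists. Folds are each peak's own value and were used to describe, rank and filter peaks within a list, except that CPN-only regions were ranked by the lower of their CPN 1 and CPN 2 folds. Many fold values in a list were whole multiples of a smallest step, 42.1% in CPN 1, 42.2% in CPN 2 and 55.8% in CSMN at a tolerance of 0.01 of a step, where 2% would fall so by chance. On the reading that a fold is the pileup plus 1 over the background plus 1, the step gives the genome background pileup of each library, the only measure of depth used here. This reading of the caller's formula is an assumption, and a pileup also depends on the length counted per read, which was not given.

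Peaks were compared by overlap of at least 1 bp, with no duplicate or self-overlapping peaks in a list to collapse. The peaks of the 3 lists were merged into regions, each classed by the libraries with a peak in it. CSMN-only regions had a CSMN peak and none in either CPN list, and CPN-only regions had a peak in both CPN lists and none in CSMN. The same counts with CPN 1 or CPN 2 as the odd library gave a background. The remaining pair then joined CSMN to a CPN library, so this background was not between replicates alone. Lists of equal length were made from the 98067 peaks of each list with the highest −log10 p, the length of the CSMN list. This kept the CSMN list whole and removed the weakest peaks of the CPN lists, so CSMN-only counts could rise but not fall. Strong regions were those with a −log10 q of at least 5 in every library that had them. Intervals for shares are Wilson 95% intervals and cover counting error only. No p-value between the cell types was computed, because CSMN had 1 library.

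Gene positions came from a RefSeq gene table of GRCm38.p6, the build named mm10, which held gene starts and ends without strand, transcription start sites or exons. Several choices fixed before the data were examined were therefore adapted. Regions were assigned to the nearest protein-coding gene body within 100 kb of their strongest summit in place of the nearest transcription start site, and 86.3% of regions were assigned. A peak within 1 kb of either gene end stood in for a peak at a promoter, and exons and introns were not distinguished. The search for transcription factor motifs by class needed the genome sequence and was not run. All 230 entries of the 13 gene lists were matched, 229 by symbol and 1 by an older symbol, giving 219 distinct genes.

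The groups, gene lists, definitions of classes, overlap rule, random lists and most alternatives were chosen before the data were examined. For each gene list, the CSMN-only share of CSMN-only plus CPN-only regions was placed among 10000 random lists matched gene by gene on the number of regions in 25 bins. A list was said to stand apart only if it lay outside the middle 95% and did not do so with a CPN library as the odd library. On simulated regions for the 21887 genes, with 30 simulations each, the CSMN list was called in 3.33% of simulations with no shift, 86.7% with the odds multiplied by 1.5 and 100% with the odds multiplied by 2. The CPN list was called in 6.67%, 90% and 100%, and the microglia list, with few regions, in 10%, 16.7% and 30%. The simulations drew every region outside the list at the same odds, so genes did not differ in balance as they do in the data. These rates therefore do not give the power of the comparison on the real counts. Overlaps computed here differed from those of bedtools 2.31.1 by 0 peaks over all pairs.

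The genes named were Fezf2, Mir193b, Mir365-1, Mapk8 and Bcl11b, the 4 genes of each list with the largest difference between CSMN-only and CPN-only regions, the nearest genes of the 10 strongest CSMN-only and the 10 strongest CPN-only regions, and the 10 genes with the largest excess in each direction. Ntng1, Gpr17 and Mag, and Hspb3, Pex5l, Rorb, the microRNA genes and window genes of the closing section, were named after their values were seen. The values of 1 further gene that the rule named are not reported here. The identity of the cluster as Mir193b and Mir365-1 is knowledge of the study and not from the labels. The alternatives were 50% reciprocal overlap, summits within 250 bp, a −log10 q of at least 5, equal list lengths, leaving out each CPN library, strong regions, gene bodies with 10 kb either side and a 2.5 kb window at gene ends. The numbers of strongest peaks examined, the search for them in lists of equal length, equal list lengths at the named loci, the alternatives for microRNA genes, the removal of windows dense in gene families and the tests of explanations were added after the data had been seen. A window dense in gene families was a 1 Mb window with at least 10 protein-coding genes whose symbol stem was shared by at least 5 genes of the window, and there were 123. Provisional Gm, LOC and Rik symbols were counted as a single stem, so such a window need not hold a true gene family. A window with fewer than 10 such genes did not count, even where its genes belonged to a family. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.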

Results

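Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in FACS-sorted mouse cortical projection neurons. Callosal projection neurons (CPN) connect the hemispheres and were represented by 2 libraries. Corticospinal motor neurons (CSMN) project to the spinal cord and were represented by 1 library. The peak lists held 134018 peaks covering 54.7 Mb in CPN 1, 158779 peaks covering 47.2 Mb in CPN 2 and 98067 peaks covering 39.7 Mb in CSMN. Read totals were not given in the sources used here, so depth was approached from the lists alone. The genome background pileup implied by the steps of the fold values was 7.65 in CPN 1, 5.84 in CPN 2 and 10.5 in CSMN, while the median peak fold within each list was 3.82, 3.68 and 2.86. With a single CSMN library the difference between the cell types had no replicate check on the CSMN side and no test between the groups was made. The difference between CPN 1 and CPN 2 served as the spread between replicates. Wilson 95% intervals are given for shares and cover counting error only.

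The title of the series concerns a microRNA cluster downstream of Fezf2, taken here as the cluster of Mir193b and Mir365-1. Around this cluster (mm10 chromosome 16, Mir193b at 13449523 to 13449601 and Mir365-1 at 13453840 to 13453926), 3 regions had a peak in all 3 libraries and 2 regions were CPN-only, meaning a peak in both CPN libraries and none in CSMN. No region within 10 kb of the cluster was CSMN-only. The CPN-only region nearest to the cluster lay at 13454185 to 13454612, 258 bp beyond Mir365-1, with a fold of 2.82 in CPN 1 and 2.54 in CPN 2. The other CPN-only region lay at 13460865 to 13461357, 6938 bp beyond Mir365-1, with a fold of 3.02 in CPN 1 and 3.81 in CPN 2. The accessible region nearest to Mir193b, at 13447412 to 13448687 and 836 bp away, had a peak in every library, with a fold of 3.68, 4.06 and 3.11 in CPN 1, CPN 2 and CSMN. A further region between the microRNA genes, at 13451844 to 13452239, was also found in all 3 lists. The CPN-only peak beside Mir365-1 was weak, with a −log10 q of 5.46 in CPN 1 and 3.21 in CPN 2. With a −log10 q of at least 5 in every list, and with lists of equal length, it was a peak of CPN 1 alone and so no longer CPN-only, whereas the region at 13460865 to 13461357 was CPN-only in both cases. The region between the microRNA genes lost its CSMN peak under the first setting and its CPN 2 peak under the second. The same absence from CSMN was found at 39731 regions across the genome with the full lists.

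Fezf2, which encodes a transcription factor that specifies subcerebral projection neurons, did not separate the libraries. Of the 4 regions within 10 kb of Fezf2 (chromosome 14, 12338992 to 12346803), 2 were accessible in all 3 libraries, including a region that spans an end of the gene at 12344608 to 12346993. The remaining regions at Fezf2 were a peak of CPN 1 alone, with a −log10 q of 4.14, and a peak of CPN 2 alone, with 6.97. Mapk8, which encodes the kinase JNK1, had a peak in all 3 libraries at an end of the gene (chromosome 14, 33446587 to 33447618), with a fold of 17 in CPN 1, 15.1 in CPN 2 and 10.7 in CSMN, and no CSMN-only or CPN-only region. Bcl11b (chromosome 12, 107910403 to 108004145), which encodes CTIP2, a transcription factor of subcerebral neurons, had 9 regions within 10 kb in all 3 libraries, 4 CPN-only regions and 2 CSMN-only regions. With only peaks of −log10 q of at least 5 counted in every list, CSMN-only regions at Bcl11b numbered 0, and with lists of equal length Bcl11b had 3 regions of each kind.

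The CPN libraries shared more peaks with each other than either shared with CSMN. With lists cut to the same length of 98067 peaks, 81.0% of CPN 1 peaks (95% interval 80.8 to 81.3) overlapped a CPN 2 peak and 85.4% of CPN 2 peaks overlapped a CPN 1 peak. At that length 62.8% of CPN 1 peaks (62.5 to 63.2) and 63.3% of CPN 2 peaks overlapped a CSMN peak, and 64.6% and 61.6% of CSMN peaks overlapped CPN 1 and CPN 2. In base pairs, the Jaccard index was 64.4% for the CPN pair, 49.2% for CPN 1 with CSMN and 47.7% for CPN 2 with CSMN. Equal length did not equalize peak strength. A −log10 q of 5 was reached by 97081 CPN 1, 103866 CPN 2 and 54115 CSMN peaks, so the CSMN list held more weak peaks. With only such peaks, sharing over both lists was 83.0% for the CPN pair and 63.2% and 61.7% for CPN 1 and CPN 2 with CSMN. Those lists differed in length, and the part of peak strength in the gap was not tested. With the full lists, 76.8% of CPN 1 peaks were found in CPN 2 and 50.5% in CSMN, 69.7% of CPN 2 peaks were found in CPN 1 and 45.5% in CSMN, and CSMN peaks were found in CPN 1 and CPN 2 at 70.4% and 70.2%. The strongest sites were common to both cell types. Of the 10000 strongest CPN 1 peaks, 0 were absent from the CPN 2 list (an interval reaching 0.0384%) and 6 from the CSMN list. Of the 10000 strongest CSMN peaks, 18 were absent from CPN 1 and 9 from CPN 2. Lower in the ranking, 0.24% of the 50000 strongest CPN 1 peaks were absent from CPN 2 and 1.43% of the 50000 strongest CPN 2 peaks were absent from CPN 1, while 14.1% and 14.6% were absent from CSMN. The full lists searched differed in length. With every searched list held at 98067 peaks, the CPN pair stood at 0.56% and 1.51% and absence from CSMN was as before, and of the 50000 strongest CSMN peaks 9.44% were absent from CPN 1 and 10.7% from CPN 2. The CPN pair is a spread between 2 libraries, and no such spread could be measured for CSMN.

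**Figure D1:**
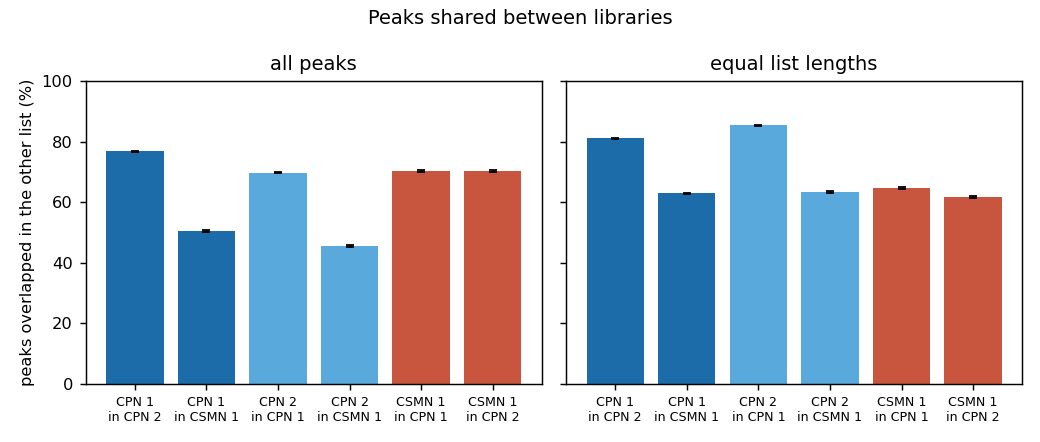
Share of each library's peaks (in percent, bars, with Wilson 95% intervals as black lines) overlapped by at least 1 bp in another library's list, for the full lists and for lists of 98067 peaks each. At equal lengths the CPN pair stands at 81.0% and 85.4%, above the values of 61.6% to 64.6% for pairs with CSMN. The CSMN list of that length holds more weak peaks than the CPN lists.

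**Figure D2:**
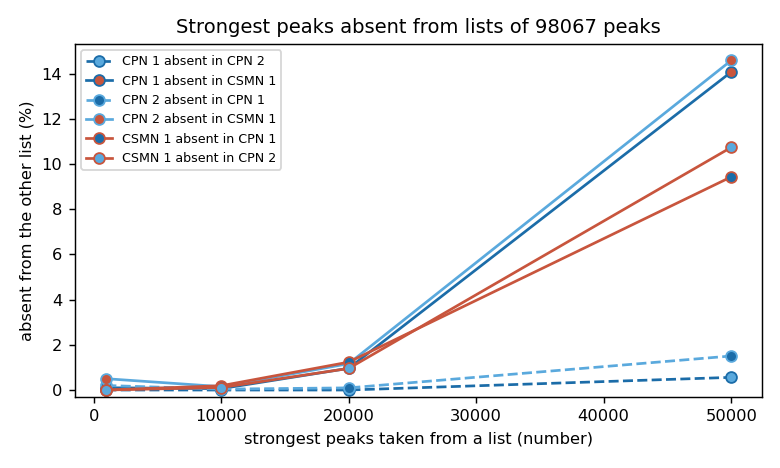
Share of the strongest peaks of a list (vertical axis, in percent, against the number of peaks taken) that have no overlapping peak in another list, each searched list being held at 98067 peaks. The dashed lines show the CPN pair and the solid lines the pairs with CSMN, and the marker fill shows the list that was searched, with 0.56% of the 50000 strongest CPN 1 peaks absent from CPN 2 and 14.1% absent from CSMN.

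Merging the lists gave 204313 regions, of which 62435 had a peak in all 3 libraries. There were 24009 CSMN-only regions and 39731 CPN-only regions, so CSMN-only regions made up 37.7% of these 2 classes together (95% interval 37.3 to 38.0). CPN 1 alone held 26300 regions and CPN 2 alone held 42701. With equal list lengths these counts were 31772 for CSMN, 13381 for CPN 1 alone and 11393 for CPN 2 alone. Regions that joined CSMN to a single CPN library were few, with 4303 shared with CPN 1 and 4834 shared with CPN 2. When CPN 1 or CPN 2 was treated as the odd library in place of CSMN, the regions shared by the remaining pair numbered 4834 and 4303 against the 39731 CPN-only regions. Most CSMN-only regions were weak, since 14.4% of them reached a −log10 q of 5, compared with 75.5% of the CSMN peaks in regions of all 3 libraries. With strong peaks required in the libraries that had them, 3463 CSMN-only and 23967 CPN-only regions remained. The direction of the balance turned with equal list lengths, where CSMN-only regions made up 58.1%. That setting trimmed the CPN lists alone, so CSMN-only regions could not become fewer. Without CPN 1 or CPN 2 the CPN-only regions, then resting on a single library, numbered 86501 and 66398. The definition is uneven, as it asks for absence from 2 lists on the CSMN side and for presence in 2 lists on the CPN side.

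Auts2 and Camta1 were among the 10 genes with the largest excess of CPN-only regions. Auts2, linked to neurodevelopmental disorders, had 48 CPN-only and 4 CSMN-only regions. Camta1, which encodes a calmodulin-binding transcription activator, and Celf2, which encodes an RNA-binding splicing regulator, each had 42 CPN-only and 7 CSMN-only regions. Msi2, an RNA-binding protein gene, had 36 against 1, and Nfia, a nuclear factor I gene of neural development, had 36 against 4. Dab1, which encodes the intracellular adaptor of reelin signaling, had 40 against 8, Frmd4a and Prkce each had 35 against 4, and Npas3 had 35 against 5. The zinc finger gene Zfp970 had 35 against 0. Each of these 10 genes also had more CPN-only than CSMN-only regions among strong regions, with 19 against 0 at Msi2 and 35 against 1 at Auts2, and with lists of equal length, with 34 against 6 at Auts2. Both settings reuse the peaks by which the genes were picked and give no independent support. Over the genome, strong regions numbered 23967 CPN-only and 3463 CSMN-only. A ranking by difference also favors genes with many regions, as Auts2 had 159 against a median of 5 per gene with a region.

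Of the 10 genes with the largest excess of CSMN-only regions, 6 carried provisional Gm or Rik names. Gm15319 on chromosome 8 had 54 CSMN-only and 0 CPN-only regions, of which 48 were strong, and its neighbor Gm40469 had 22 against 0. In the same part of chromosome 8, 9530057J20Rik had 32 against 1 and 4930467E23Rik had 24 against 0. Cwc22, which encodes a splicing factor, had 34 against 1. The prolactin family gene Prl2c3 and the spindlin family gene Spin2f each had 24 against 0, and Gm5373 and A530032D15Rik each had 23 against 0. Dlg2, which encodes the postsynaptic scaffold protein PSD-93, had 32 against 8, but among strong regions Dlg2 had 2 against 8, so its direction turned. Over the genome the strong setting kept 3463 of 24009 CSMN-only and 23967 of 39731 CPN-only regions, so it favored such a turn.

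The strongest CSMN-only regions, ranked by the authors' fold within the CSMN list, lay at or near Gm51598 and Gm51572 on chromosome 8. The highest, at 55519149 to 55519883, was 18960 bp from Gm51598 with a fold of 16.8, and Gm51572 had a region 1607 bp away with a fold of 14.8. Gm51598 was nearest to 2 further regions of the top 10. Others of the 10 were nearest to Nus1, Apba2, Hrh1 and Gm4301 or lay inside Ppp2r2b (chromosome 18, 42975887 to 42976017, fold 8.76) and Gm2832. Hrh1 encodes a histamine receptor and Apba2 a neuronal adaptor protein. The strongest CPN-only region, on chromosome 1 at 122357130 to 122357249, had no protein-coding gene within 100 kb and reached a fold of 35.7 in CPN 1 and 52.5 in CPN 2. A CPN-only region 18744 bp from Cspg5, a brain proteoglycan gene, had folds of 33.8 and 50.4 and was 121 bp wide. CPN-only regions of the top 10 also lay inside Atf2 (chromosome 2, 73867896 to 73868033, folds 16.2 and 19.9) and Gm40365 and near Tmem125, Dbx2 and Rgs7. Of these 10 regions, 4 had a CPN 1 peak under 150 bp wide.

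For the identity genes of the compared neurons, the balance did not follow the names of the lists. The list of CSMN and subcerebral neuron genes had 82 CSMN-only and 195 CPN-only regions, a CSMN-only share of 29.6%, and the list of CPN and upper-layer genes had 75 and 190, a share of 28.3%. Over all genes the share was 34.3%, from 18159 CSMN-only and 34788 CPN-only regions. Of the 26 CSMN genes, 17 had more CPN-only regions and 5 had more CSMN-only regions. Of the 26 CPN genes, 19 had more CPN-only regions and 5 had more CSMN-only regions. In the CSMN list, Cdh13, a cadherin gene, had 32 CPN-only and 7 CSMN-only regions, Sox5, which controls the timing of deep-layer neuron generation, had 28 and 11, the ephrin receptor gene Ephb1 had 24 and 8, and Ldb2, a cofactor of LIM-domain factors, had 17 and 3. In the CPN list, the upper-layer factor gene Cux1 had 19 and 3, Limch1 had 17 and 1, Frmd4b had 19 and 4, and Chn2 had 12 and 1. Among 10000 random lists of genes matched on regions per gene, the CSMN list stood at percentile 39.3 and the CPN list at percentile 26.8. Neither stood outside the middle 95% of the random lists, which ran from 21.7% to 43.1% for the CSMN list and from 22.3% to 43.5% for the CPN list. With lists of equal length the shares were 52.5% and 50.7%, so the direction of the counts turned, while the percentiles of 36 and 25 stayed inside.

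The other neuronal lists also held more CPN-only than CSMN-only regions. Corticothalamic and subplate genes had 27 CSMN-only and 54 CPN-only regions (percentile 59.5), with Zfpm2 and Tle4 each at 3 and 9, Hs3st4 at 1 and 7 and Foxp2 at 4 and 7. Pan-excitatory neuron genes had 26 and 72 (percentile 27.3), with Rbfox3, which encodes NeuN, at 4 and 22, the glutamate receptor gene Grin2b at 2 and 12, Map2 at 2 and 8 and Dcx at 0 and 5. Axon guidance genes had 126 and 318 (percentile 30.6), and 25 of their 30 members had more CPN-only regions, among them Slit3 with 11 and 31, Plxna4 with 3 and 20, Ephb1 with 8 and 24 and Ephb2 with 2 and 17. Dendrite morphology genes, listed because the title names dendritic morphology, had 53 and 168 (percentile 11.5), with Kalrn at 9 and 28, the neurotrophin receptor gene Ntrk2 at 2 and 20, Dscam at 3 and 20 and Cux1 at 3 and 19. Activity-regulated genes had 17 and 33 (percentile 47.1). Within that list Arc had 4 CSMN-only and 0 CPN-only regions and Bdnf had 3 and 0, whereas Fos had 0 and 5 and Egr2 had 0 and 3. Among strong regions Arc had 0 and 0 and Bdnf 1 and 0. With lists of equal length, Egr2 stood at 1 and 1, Foxp2 turned to 7 CSMN-only and 1 CPN-only regions and Slit3 to 16 and 12, and 8 of the 13 lists had a CSMN-only share over 50%.

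Marker lists of other cell types were included because a sorted sample could hold such cells. Astrocyte genes had 8 CSMN-only and 35 CPN-only regions, the glutamate transporter genes Slc1a3 and Slc1a2 standing at 2 and 11 and at 1 and 4, and Sox9 and Fgfr3 each at 0 and 4, though with lists of equal length Sox9 turned to 2 and 1 and Slc1a2 stood at 1 and 1. Oligodendrocyte lineage genes had 9 and 38, with the progenitor receptor gene Pdgfra at 2 and 15, the myelin gene Mbp at 2 and 10, Cspg4 at 0 and 4 and Olig1 at 1 and 3. Microglia genes had 3 and 14, with Irf8 at 0 and 6, C1qb at 0 and 3, C1qa at 0 and 2 and Spi1 at 1 and 0. With lists of equal length Irf8 and C1qa each stood at 1 and 1. With the full lists, the astrocyte, oligodendrocyte and microglia genes had the lowest percentiles, at 5.92, 8.02 and 8.44, and stayed inside the random range. At equal list lengths they stood at 27.6, 14.3 and 51.3, and the endothelial and mural genes were lowest at 5.79. Endothelial and mural genes had 23 and 58 (percentile 33.6), with Flt1 at 2 and 13, Erg at 5 and 14, Pecam1 at 0 and 6 and Cspg4 at 0 and 4. Cortical progenitor genes had 29 and 65 (percentile 50.2), with Sox2 at 4 and 18, Hes1 at 2 and 10, Emx2 at 2 and 7 and Gli3 the other way at 15 and 10. Interneuron genes had 32 and 49 (percentile 72.9), with Prox1 at 4 and 10, Dlx2 at 0 and 5, Npy at 1 and 6 and Adarb2 the other way at 14 and 6. Among strong regions, a setting that removed a larger part of the CSMN-only than of the CPN-only regions, Adarb2 turned to 2 and 4 and Gli3 stood at 3 and 3. With genes bounded by the gene body and 10 kb either side, the astrocyte list moved to a CSMN-only share of 8.33% at percentile 0.71, outside the random range. With CPN 2 as the odd library, 3 lists stood outside, namely the interneuron list at percentile 0.13, the endothelial and mural list at 99.6 and the progenitor list at 98.2. That setting sets regions of CPN 2 alone against regions joining CPN 1 to CSMN. A list could thus leave the range with a CPN library as the odd library.

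**Figure D3:**
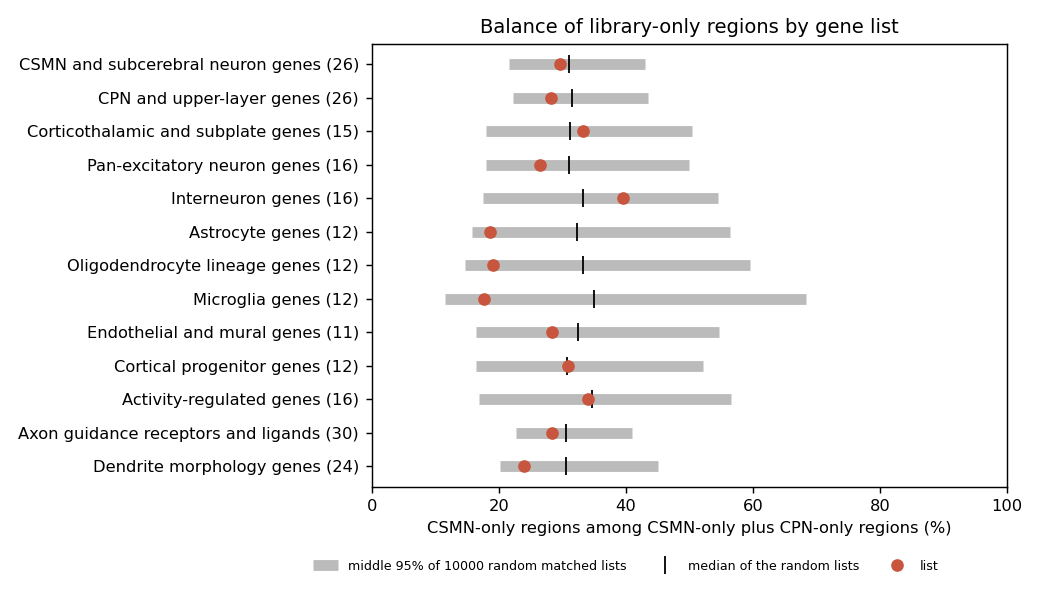
CSMN-only regions as a share of CSMN-only plus CPN-only regions (horizontal axis, in percent) for the 13 gene lists, with the number of genes that had a region in brackets. Gray bars span the middle 95% of 10000 random matched lists and black ticks their medians, and every list lies inside its bar, the CSMN list at 29.6% and the CPN list at 28.3%.

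Peaks at gene ends were largely common to the libraries. Of 21887 protein-coding genes, 69.2% in CPN 1, 70.3% in CPN 2 and 66.7% in CSMN had a peak within 1 kb of either end, and 14033 genes had such a peak in all 3. With lists of equal length the order turned, with 66.4%, 66.0% and 66.7%. Both CSMN genes and CPN genes had 25 of 26 members with such a peak in each CPN library and 24 of 26 in CSMN. In the CSMN list the member missing from CSMN alone was Ntng1. With lists of equal length both lists had 24 of 26 in every library. All 12 endothelial and mural genes and all 12 progenitor genes had a gene-end peak in every library, though with a −log10 q of at least 5 the endothelial and mural genes had 9 of 12 in CSMN and 12 of 12 in each CPN library. Oligodendrocyte genes had 10 of 12 in each CPN library and 7 of 12 in CSMN, the difference being Pdgfra, Gpr17 and Mag, but with lists of equal length they had 9, 8 and 7 of 12 in CPN 1, CPN 2 and CSMN. Microglia genes had 7, 6 and 5 of 12 in CPN 1, CPN 2 and CSMN, and 6, 6 and 3 with a −log10 q of at least 5. The corresponding counts were 10, 11 and 10 of 12 for astrocyte genes and 14, 16 and 14 of 16 for interneuron genes, the latter at 14, 15 and 11 with a −log10 q of at least 5. They were 14, 15 and 14 of 16 for pan-excitatory genes and 15, 14 and 15 of 15 for corticothalamic and subplate genes. Activity-regulated genes stood at 15, 15 and 14 of 16, axon guidance genes at 28, 29 and 27 of 30, and dendrite morphology genes at 23 of 24 in every library. The 95% intervals of the CPN and CSMN shares overlapped for each of these lists, including 55.2 to 95.3% against 32.0 to 80.7% for the oligodendrocyte genes. The same genes were scored in every library, so overlap of separate intervals does not show that the shares were equal.

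Regions not found in all 3 libraries lay away from gene ends. Of the regions found in all 3 libraries, 21.2% (95% interval 20.9 to 21.5) lay within 1 kb of a protein-coding gene end, compared with 3.64% (3.41 to 3.88) of CSMN-only and 4.16% (3.97 to 4.36) of CPN-only regions. The share was also low for regions of CPN 1 alone (4.42%) and CPN 2 alone (4.50%) and for those joining CSMN to CPN 1 (5.07%) or CPN 2 (4.89%). CSMN-only regions lay between genes in 54.8% of cases (54.1 to 55.4), against 42.4% of CPN-only regions, 40.3% of regions of CPN 1 alone and 40.9% of regions of CPN 2 alone. CPN-only regions lay inside gene bodies more often, at 53.4% against 41.6% of CSMN-only regions. The difference between CSMN-only and CPN-only regions in the share between genes exceeded the difference between CPN 1 alone and CPN 2 alone. Regions joining CSMN to CPN 1 or CPN 2 lay between genes in 48.9% and 48.4% of cases. A share above that of the CPN classes was thus not particular to CSMN-only regions, and no alternative was run for it.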

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

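All tests of explanations in this part were chosen after the results they bear on had been seen. Peaks on unplaced and unlocalized contigs were outside the comparisons by gene and numbered 107 in CPN 1, 139 in CPN 2 and 199 in CSMN. On the unlocalized contigs of chromosome 1 there were 4, 6 and 93 peaks.

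Strong CSMN-only regions gathered in a few windows, as the 10 densest 1 Mb windows held 487 of 3463 such regions, led by 119 on chromosome 8 from 20000001 to 21000000, where Gm15319 and Gm40469 lie, and including a window of Zfp genes on chromosome 4 and 2 windows of chromosome Y. These windows held 14.1% of the regions and the highest of 1000 equal random draws of strong CSMN peaks reached 3.38% in theirs, but the gathering prompted this test, so greater depth of the CSMN library alone stays open. Sequence present in several copies stays open. Of the 487 regions, 93 (19.1%) lay in windows dense in gene families, against 3.86% of the regions of all 3 libraries. Only 2 of the 10 windows met that rule. The leading window on chromosome 8, the window of Zfp genes and those of chromosome Y did not, so this share cannot measure copied sequence. Over all strong CSMN-only regions, tested first, the share was 8.52%, against 2.77% of strong CPN-only regions, 2.47% and 3.79% of those of CPN 1 and CPN 2 alone, and 4.46% and 7.76% of those joining CSMN to CPN 1 and CPN 2. Open chromatin of the CSMN cell type cannot be told apart from a trait of this library or its mice, with 0 further CSMN libraries to compare, and a difference in copy number between mice was not tested. Chromosome Y as a whole held 333 peaks in CPN 1, 373 in CPN 2 and 594 in CSMN, and the cause was not tested.

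CPN-only regions outnumbered CSMN-only regions with the full lists. Lower depth of the CSMN library is argued against by its genome background pileup of 10.5, above the 7.65 and 5.84 of the CPN libraries, on the assumed reading of the fold values. A pileup also rises with the length counted per read, which was not given, so it is not a count of reads. Of the 39731 CPN-only regions, 94.0% had a CPN 1 fold below 6.28, the median of CPN 1 in regions of all 3 libraries, but so had 99.98% of the regions of CPN 1 alone, so weakness of the missing regions decides nothing. Weaker enrichment in the CSMN library and fewer open regions in the CSMN cell type cannot be told apart with 0 further CSMN libraries. The order itself turned with equal list lengths, a setting that trimmed the CPN lists alone, where CSMN-only regions made up 58.1%.

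The strongest CPN-only regions were often very narrow. Of the 10 strongest, 4 had a CPN 1 peak under 150 bp, those at Atf2 and near Cspg5 and Rgs7 and the region on chromosome 1 at 122357130, compared with 5 of 7096 regions of all 3 libraries (0.0705%) at or above the lowest CPN 1 fold of the 10. Whether this reflects reads piled on one short sequence stays open for these 4, since their width prompted the test, and a test with the width of the merged region in place of the CPN 1 peak was tried first. No biological explanation of their width was tested.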

How the results depend on the processing

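The settings without gene family windows, with the strongest 10000 peaks, with the strongest peaks searched in lists of equal length and with equal list lengths at the named loci were chosen after the data had been seen. The CPN pair shared more peaks than either CPN library with CSMN under every overlap rule, threshold and list length tried. Over the peaks of both lists, sharing was 72.9% for the CPN pair, 58.9% for CPN 1 with CSMN and 54.9% for CPN 2 with CSMN. It was 57.1%, 44.6% and 40.0% with 50% reciprocal overlap, 69.4%, 55.1% and 51.6% with summits within 250 bp, 83.0%, 63.2% and 61.7% with −log10 q of at least 5, 83.2%, 63.7% and 62.5% with equal list lengths, and 91.2%, 82.6% and 80.4% with the strongest 10000 peaks. The CSMN-only share of 37.7% became 48.8% with 50% reciprocal overlap (37778 CSMN-only regions), 38.1% with summits within 250 bp, 12.1% with −log10 q of at least 5 (4825 CSMN-only regions), 12.6% with strong regions (3463 CSMN-only and 23967 CPN-only) and 37.0% without gene family windows. It reversed to 58.1% with equal list lengths, which left 22928 CPN-only regions. That setting removed peaks from the CPN lists only, so a move toward CSMN-only regions was built into it. Without a CPN library the CSMN-only share ran from 25.3% to 30.4% and CPN-only regions from 66398 to 86501, since presence in a single list was then enough.

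Of 91 percentiles of gene lists under 7 alternatives, 14 could not have left the middle 95% of random lists on the low side, since a share of 0 would stay inside, 5 of them with −log10 q of at least 5 and 9 with strong regions. Of the other 77, 76 stayed inside, and the astrocyte list moved to 0.71 with gene body and 10 kb either side; the cause was not tested. Near gene ends, CSMN-only regions stood at 4.10% and CPN-only at 3.92% with equal list lengths, the order of 3.64% and 4.16% turned, at 8.17% and 8.90% with a 2.5 kb window, and CPN-only at 4.45% with −log10 q of at least 5. Without a CPN library these shares ran from 3.89% to 4.14% for CSMN-only and from 4.28% to 4.64% for CPN-only regions. Genes with a gene-end peak came to 75%, 76.3% and 72.9% in CPN 1, CPN 2 and CSMN with a 2.5 kb window, 66.2%, 66.4% and 61.8% with −log10 q of at least 5, and 66.4%, 66.0% and 66.7% with equal list lengths, where the order turned. With −log10 q of at least 5, CSMN-only regions numbered 0 at Bcl11b, the cause of which was not tested, and Fezf2 and Mapk8 had 0 CSMN-only and 0 CPN-only regions as before. The microRNA cluster had 2 CPN-only regions with −log10 q of at least 5, but a different pair without the region beside Mir365-1, and 1 with equal list lengths, since peaks of CPN 2 or CSMN then fell below the threshold. No paired analysis was possible because the groups share only replicate number 1 and the results come from no test. The alternatives for motifs were not run for want of the genome sequence, and sharing of the CPN pair has no value without a CPN library. Depth and enrichment limit what absence of a peak means.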

Other observations

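The microRNA genes beyond the cluster were counted, and which of them are named, and the alternatives for them, were chosen after the values were seen. Of 1228 microRNA genes, 356 in CPN 1, 356 in CPN 2 and 270 in CSMN had a peak within 1 kb, and 233 had such a peak in all 3 libraries. A peak in CSMN and neither CPN library was found at 21 microRNA genes, among them Mir379, Mir411, Mir299a and Mir381 of a large imprinted cluster and Mir99b, Mirlet7e and Mir125a, which lie next to each other. A peak in both CPN libraries and not in CSMN was found at 60, among them Mir365-1, the neighbors Mir23a, Mir27a and Mir24-2, and Mir219a-2, a microRNA gene of oligodendrocyte development. Among protein-coding genes the order was the same, with a gene-end peak in CSMN alone at 308 and in both CPN libraries alone at 730. Neighboring microRNA genes can share a peak, so the microRNA counts are not of independent sites. With a −log10 q of at least 5 the counts were 5 and 47 and included none of the microRNA genes named here, Mir365-1 among them. With lists of equal length they were 39 and 27, so the order turned, and the named CPN-only genes were no longer among them.

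Strong CSMN-only regions were also looked up at the listed genes, and Hspb3, Pex5l and Rorb were named after the values were seen. The strongest lay 54915 bp from Hspb3, a gene of the CPN list, at chromosome 13, 113718506 to 113718815, with a fold of 5.21, and 74485 bp from Pex5l of the CSMN list, at chromosome 3, 33217494 to 33217888, with a fold of 4.95. Rorb, a layer 4 and upper-layer factor gene, held 3 strong CSMN-only regions inside its body, on chromosome 19 at 19001110, 19043276 and 19076490. Adarb2 held 2, beside 4 strong CPN-only regions. The CSMN list had 8 strong CSMN-only regions and 109 strong CPN-only regions, and the CPN list had 15 and 108. The CSMN-only shares were 6.84% and 12.2%, beside 12.6% over all strong regions. Among matched random lists they stood at percentiles 51.8 and 81.0, so neither list stood apart.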
